A study of Mus musculus with 6 samples.

How the data were processed

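Liver RNA from 6 samples was analysed, 3 controls and 3 with Atoh8 knockdown, all after 17 days on a 0.1% DDC diet. Groups and replicate numbers were taken from the labels. Total RNA was extracted with Trizol from frozen livers and made into Illumina libraries, per the labels' protocols. The labels give the cell type as hepatocyte and the source as liver, so the share of other liver cells in each sample is unknown.

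The authors deposited a file of raw read counts per gene for each sample and a table of FPKM values for all samples. The tools FastQC, Trim Galore, HISAT2 (listed as version 2.10), HTSeq and Cufflinks (version 2.2.1), and the genome build GRCm38 (mm10), are listed per the submitters' processing notes, with no role or order. FPKM values divide counts by transcript length and by library size and were deposited by the authors with no stated filter. Whether reads were counted by strand is not given in the sources used here, so reads of overlapping antisense genes cannot be told apart. The count files close with lines that name no gene. These showed 2.48%, 5.66% and 5.12% of reads outside genes in control replicates 1 to 3 and 4.37%, 4.18% and 4.85% in knockdown replicates 1 to 3. Ambiguous reads made up 6.87%, 4.69% and 5.00% in the controls and 6.17%, 5.96% and 5.79% in the knockdown libraries. The lines for unaligned, low-quality and multiply aligned reads were all 0, so reads shared between near-identical genes are either missing or placed without a mark. These lines were left out of library sizes and tests.

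The count files held 47729 genes, of which 22964 had a read in some library and 47310 were found by identifier in the GENCODE M21 annotation of GRCm38, which gave coordinates, GC content and transcript length. The FPKM table held 47719 genes. Reads in genes ranged from 31912058 to 37969644 per library. A floor of 3 reads corresponded to 0.079 to 0.094 CPM. Intervals and floors cover counting error only. No replicate pair agreed within sampling noise, since the chi-square per gene over sampling noise was at least 50.2 for genes with 20 or more reads in a pair.

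Counts were filtered with filterByExpr, scaled by TMM and tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on group alone. TMM factors were 0.852, 0.944 and 0.965 for the controls and 1.10, 1.04 and 1.13 for the knockdown libraries. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. CPM values use the TMM-scaled library sizes, and log2 CPM a prior count of 2. The test, its alternatives, 40 gene lists and the rule for named genes were chosen before the data were examined. The rule named Atoh8, the 10 largest increases and 10 largest decreases among called genes with a mean of at least 1 CPM, non-overlapping groups and a standard symbol, the members of each list with the smallest p (up to 4 that passed, or 2 where none did), and 15 genes of cholestatic liver. Genes named outside it are marked as chosen after their values were seen. A gene that the rule names is not reported here, and it was also left out of the test on clock genes.

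Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with a correlation estimated from each list. Camera compares a list with all other genes. The fry test, which asks whether a list's genes move on balance in one direction, and camera on ranks were alternatives. Other alternatives were median ratio size factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with quality weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of at least 0.5 in 3 libraries, the replicate number as a block, removal of mitochondrially encoded genes and the 20 most abundant genes, and each library left out in turn. An offset per library for GC content and transcript length, fitted by loess with a span of 0.3, was added after seeing the data, as was log2(FPKM + 0.1) for Atoh8.

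The edgeR test was tested on simulated data, with counts drawn from the means and library sizes of these samples and 200 genes changed. With all 6 libraries it recovered 2% of genes changed 2-fold, 74% of those changed 4-fold, 98% of those changed 8-fold and 100% of those changed 16-fold, with 3 false calls among 13483 genes. Without control replicate 1 it recovered 64%, 96%, 100% and 100%, with 19 false calls among 13941 genes. Camera with an estimated correlation recovered a simulated list of 25 genes raised 2-fold with all 6 libraries and did not without control replicate 1. Each gene was drawn independently, so the simulated data held no correlation between genes and no library that stood apart as a whole. Recovery and false calls may therefore differ in the real data.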

Results

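RNA was sequenced from livers of C57BL/6 mice kept for 17 days on a diet with 0.1% DDC, a porphyrinogenic compound that injures bile ducts and hepatocytes. There were 3 control libraries and 3 libraries with knockdown of Atoh8, which encodes a basic helix-loop-helix transcription factor. The sample titles call the controls WT, whereas the series design names them shNC and the knockdown shAtoh8. The labels name liver as the source and hepatocyte as the cell type, and the protocol describes RNA from removed livers. Reads in genes per library came to 35438096, 36970491 and 31912058 for control replicates 1 to 3, and to 37584160, 36915731 and 37969644 for knockdown replicates 1 to 3. The labels do not say whether the replicates of a group were separate animals, so the p-values measure only the spread between these samples, which may be technical. The comparison asked which transcripts differed in abundance between the livers labelled as Atoh8 knockdown and the controls under the same diet.

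Atoh8 (ENSMUSG00000037621, GRCm38 chromosome 6, 72206177 to 72235577, minus strand) was lower in all 3 knockdown libraries than in any control. It stood at 63.8, 16.8 and 16.4 CPM in control replicates 1 to 3 and at 10.2, 9.83 and 5.64 CPM in knockdown replicates 1 to 3. The log2 fold change was -1.92 (SE 0.58), and with an edgeR quasi-likelihood test and Benjamini-Hochberg adjustment over all genes it did not pass (adjusted p = 0.197). Control replicate 1 set much of that value. With that library left out Atoh8 fell by 0.95 on the log2 scale (SE 0.23, edgeR adjusted p = 0.0115).

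**Figure D1:**
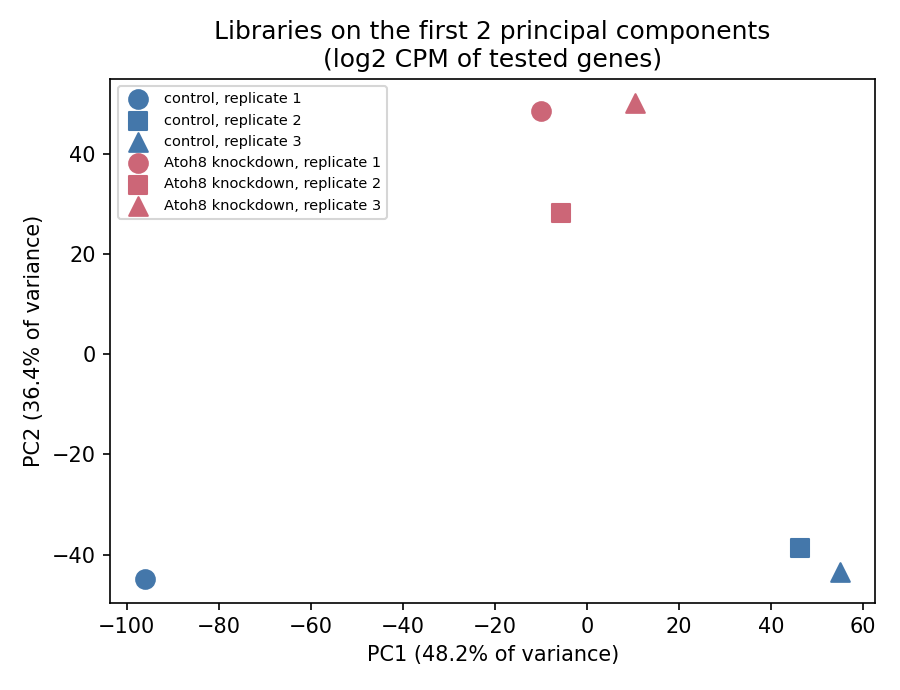
The 6 libraries on the first 2 principal components of log2 CPM, with the share of variance on each axis, coloured by group and shaped by replicate. Control replicate 1 lies at -96.0 on the first component and the other controls at 46.4 and 55.0, with the knockdown libraries between them. The second component parts the groups.

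Control replicate 1 stood apart from the rest. The first principal component held 48.2% of the variance and separated it from control replicates 2 and 3, whereas the second held 36.4% and separated the groups. Over genes, the Pearson correlation of log2 counts of control replicate 1 with control replicates 2 and 3 was 0.902 and 0.889, against 0.983 between those. Mitochondrially encoded genes took 2.43% of its gene reads, against 6.94% and 5.35% in the other controls and 3.48%, 4.44% and 4.61% in the knockdown libraries. The Y-linked gene Ddx3y stood at 9.67 CPM in control replicate 1, at 92.6 and 110 CPM in the other controls and between 28.0 and 38.4 CPM in the knockdown libraries. Gpnmb, a gene of lipid-associated macrophages, stood at 98.0 CPM in control replicate 1, at 10.1 and 7.37 CPM in the other controls and between 47.0 and 73.6 CPM in the knockdown libraries. Ddx3y, Xist and Gpnmb were singled out after their values were seen.

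In the knockdown livers 11 of 25 cell cycle genes passed edgeR over all genes as higher, as did Spp1. Alas1 and Sult1e1 passed as lower. Cdc20, the activator of the anaphase-promoting complex, went from 0.552 ± 0.126 CPM (SD, n = 3) in controls to 26.2 ± 8.01 CPM (SD, n = 3), and Ccnb1, which encodes cyclin B1, from 0.584 ± 0.221 to 16.7 ± 4.57 CPM. Spp1, which encodes the secreted matrix protein osteopontin, rose from 36.4 ± 5.20 to 463 ± 122 CPM. Among the genes that fell, Alas1, the rate-limiting enzyme of heme synthesis in liver, went from 2865 ± 696 to 728 ± 176 CPM. Sult1e1, the estrogen sulfotransferase, fell from 57.6 ± 39.4 to 2.35 ± 0.359 CPM.

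**Figure D2:**
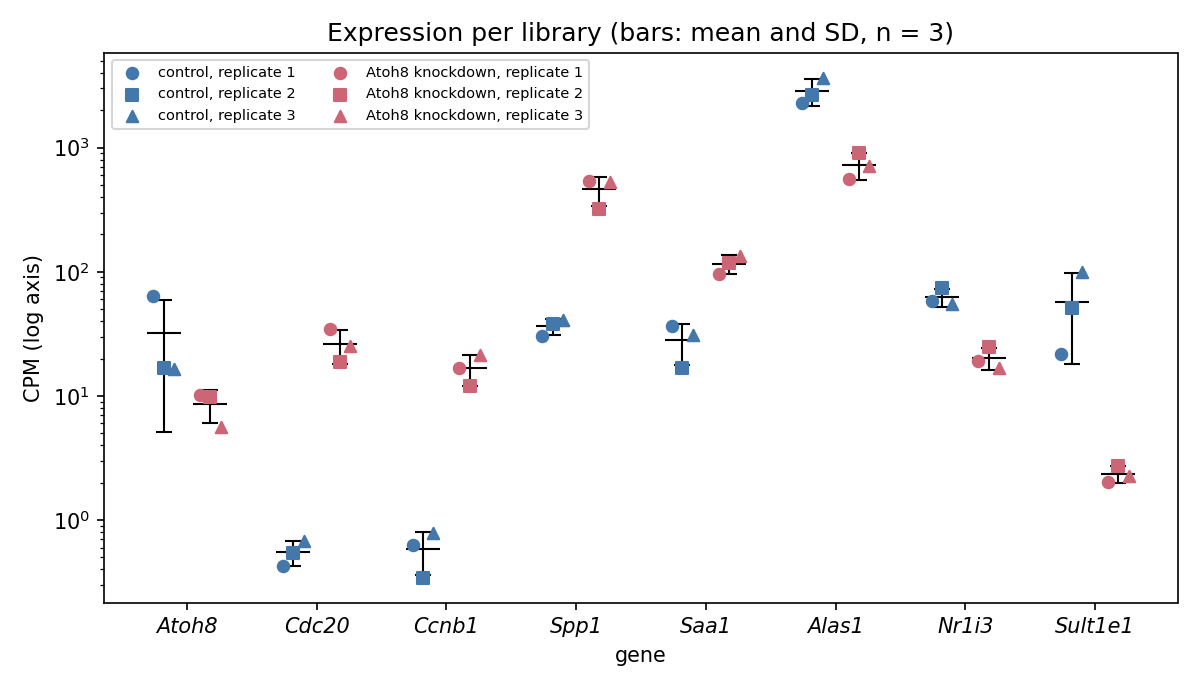
CPM of 8 genes in each library on a log axis, coloured by group and shaped by replicate, with bars for the mean and SD of 3 libraries. Cdc20, Ccnb1, Spp1 and Saa1 are higher and Alas1, Nr1i3 and Sult1e1 lower in every knockdown library than in any control. For Atoh8, control replicate 1 lies at 63.8 CPM, far above the other controls.

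Of 13767 genes tested, 102 were higher and 17 lower in the knockdown livers by the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Their median log2 fold changes were 3.27 and -1.63. The groups did not overlap for any of these 119 genes, and for 23.1% of all tested genes, where chance gives 10%. With control replicate 1 left out, 2348 genes were higher and 2284 lower of 14222 tested, and all 119 genes were among them with the same direction. All libraries of that fit are also in the main one, so the shared calls are not independent support. The log2 difference between the knockdown libraries and control replicates 2 and 3 followed GC content over genes (Spearman 0.352). No offset for GC content was applied in the fit without control replicate 1. The counts fell to 0 without control replicate 2, knockdown replicate 1 or knockdown replicate 3, to 21 without control replicate 3 and to 10 without knockdown replicate 2. At an unadjusted p under 0.05, the fits with 0 calls had 1633, 1130 and 1224 genes.

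The 10 largest increases included Cdc20 (log2 fold change 5.56, SE 0.36, edgeR adjusted p = 0.0096) and Ccnb1 (4.84, SE 0.40, edgeR adjusted p = 0.0099). Nuf2 and Ttk, which act at the kinetochore and the spindle checkpoint, rose by log2 fold changes of 5.40 (SE 0.70) and 4.90 (SE 0.55). The phosphatase gene Cdc25c, the kinesin gene Kif4 and Iqgap3 rose by 5.66, 4.99 and 5.26. Pif1, a DNA helicase gene, had 2 reads in all control libraries together and 367 in the knockdown libraries, a ratio of 144 with an exact 95% counting interval of 39.5 to 1191. Akr1c18 and Spink1 also rose, from 0.108 to 5.39 CPM and from 0.0707 to 3.14 CPM.

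Among the 10 largest decreases, Alas1 fell by 1.98 on the log2 scale (SE 0.29, edgeR adjusted p = 0.0368) and Sult1e1 by 4.61 (SE 0.57, edgeR adjusted p = 0.0282). Csad, an enzyme of taurine synthesis, fell from 422 ± 36.5 to 111 ± 16.2 CPM, and the carboxylesterase Ces1d from 885 ± 229 to 248 ± 33.0 CPM. Ces1d belongs to a family of similar genes, so its reads are less certain. Nr1i3, which encodes the xenobiotic sensor CAR, fell from 62.2 ± 9.92 to 20.2 ± 4.08 CPM. Gpr135, Treh, Txndc15 and Urad fell by 3.96, 1.84, 1.64 and 1.63 on the log2 scale.

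Of the cell cycle genes, 11 of 25 rose and none fell over all genes tested, and 22 rose when adjusted over the list alone. All 25 had positive fold changes, with a median log2 fold change of 2.94. Birc5, Foxm1 and Cdk1 rose by log2 fold changes of 3.49 (SE 0.35), 4.07 (SE 0.42) and 3.72 (SE 0.40), whereas the proliferation marker Mki67 did not pass (3.16, SE 1.09, edgeR adjusted p = 0.243), with 0.0331, 0.803 and 4.13 CPM in control replicates 1 to 3. Without control replicate 1 Mki67 passed too (2.63, SE 0.55, edgeR adjusted p = 0.00598). The list stood apart from other genes by camera with a preset correlation (adjusted p = 5.47e-22). It did not pass with the correlation estimated from each list (adjusted p = 0.269 with an estimated correlation). None of the 36 lists tested passed with an estimated correlation, and the lists described here were fixed before the data were examined.

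**Figure D3:**
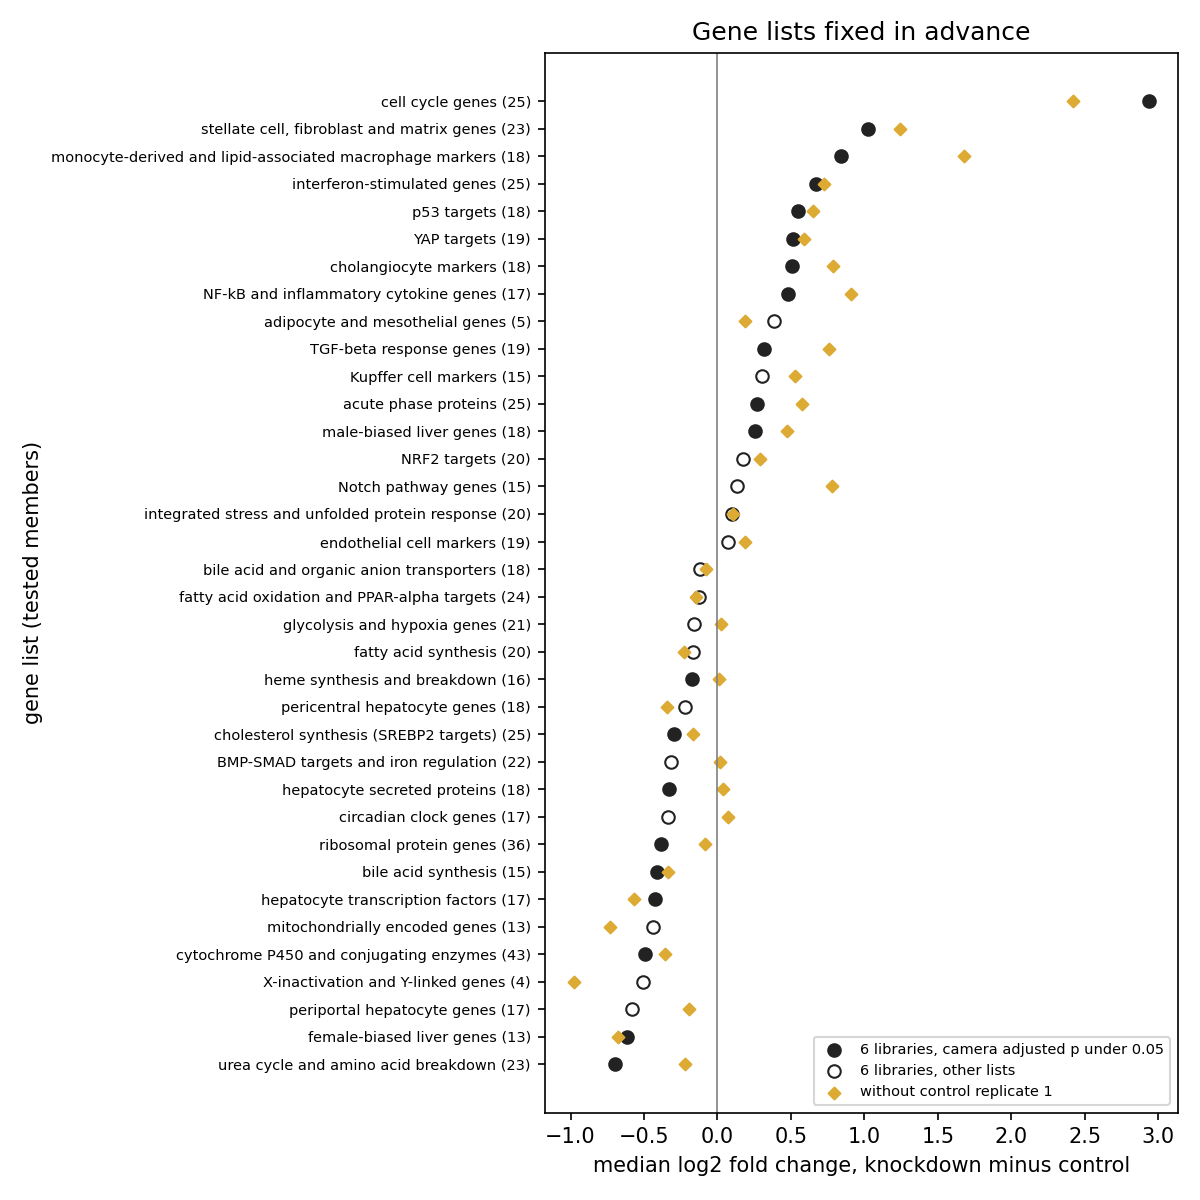
Median log2 fold change, knockdown minus control, of the tested members of each gene list, with the number of tested members in brackets. Filled circles mark lists past an adjusted p of 0.05 by camera with 6 libraries, open circles the other lists, and diamonds the medians without control replicate 1. Cell cycle genes lie highest at 2.94, and 2.42 without control replicate 1.

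Camera called matrix and macrophage genes higher as lists in the knockdown livers, with 1 member past edgeR on its own. For the macrophage list control replicate 1 lay at the knockdown level. Of the stellate cell, fibroblast and matrix genes, 1 of 23 rose over all genes tested and 12 when adjusted over the list alone, with a median log2 fold change of 1.02. The list passed by camera (adjusted p = 8.67e-10, adjusted p = 0.349 with an estimated correlation). The member that rose was Acta2, which encodes smooth muscle actin, with 2 reads in the controls and 135 in the knockdown libraries, a ratio of 52.9 with an exact 95% counting interval of 14.4 to 441. Col1a1, a fibrillar collagen gene, stood at 6.31 ± 5.55 and 27.6 ± 6.31 CPM (SD, n = 3) and did not pass (edgeR adjusted p = 0.163). Control replicate 1 had 12.7 CPM of Col1a1 against 3.27 and 2.96 CPM in the other controls, and without that library it rose by a log2 fold change of 3.16 (edgeR adjusted p = 0.000102).

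Of the markers of monocyte-derived and lipid-associated macrophages, 0 of 18 passed, over all genes tested by edgeR or adjusted over the list alone, while the list's median was 0.84 and camera gave an adjusted p of 0.0001965 (adjusted p = 0.492 with an estimated correlation, and adjusted p = 0.224 by the fry test). In the fit without control replicate 1, 14 members were higher and 1 lower. In control replicate 1 the median member lay 1.61 above the other controls on the log2 scale, and in the knockdown libraries 1.59 above them. The list therefore did not part control replicate 1 from the knockdown libraries. The members with the smallest p were Cd63, at 112 and 67.3 CPM in controls and knockdown, and Plac8, at 2.29 and 5.44 CPM. The 15 Kupffer cell markers and the 19 endothelial markers did not pass by camera (adjusted p = 0.126 and 0.841), and no member passed by edgeR. Without control replicate 1, camera called the Kupffer cell list higher (adjusted p = 0.0219), with 8 members higher and 1 lower, but not with an estimated correlation (adjusted p = 0.623 with an estimated correlation). With all libraries 12 Kupffer cell markers had positive and 3 negative fold changes. The scavenger receptor gene Cd163, among the negative ones, stood at 28.9 ± 11.6 CPM in controls and 10.1 ± 2.77 CPM in knockdown (edgeR adjusted p = 0.140). Folr2 stood at 6.81 ± 1.09 CPM in controls and 10.1 ± 0.748 CPM in knockdown (edgeR adjusted p = 0.301).

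Spp1 and Prom1 were the cholangiocyte markers that rose, 2 of 18 over all genes tested and 5 adjusted over the list alone. Their log2 fold changes were 3.67 (SE 0.28) and 2.95 (SE 0.42), and the list passed by camera (adjusted p = 0.00182, adjusted p = 0.465 with an estimated correlation). Krt19, the keratin that marks bile duct cells, had 0 to 5 reads per library and was not tested. Epcam stood at 0.485 ± 0.246 CPM in controls and 0.972 ± 0.419 CPM in knockdown (edgeR adjusted p = 0.465), and Sox9 at 10.2 ± 2.73 and 10.7 ± 2.28 CPM (edgeR adjusted p = 0.944). The YAP targets, with 0 of 19 members past edgeR over all genes and 3 adjusted over the list alone, passed as a list by camera (adjusted p = 0.0102, adjusted p = 0.465 with an estimated correlation). The YAP list was not called without control replicate 3 (camera adjusted p = 0.0542). Among its members F3 and Cyr61 had the smallest p, with log2 fold changes of 1.48 and 1.08. The 15 Notch pathway genes did not pass (camera adjusted p = 0.166), with 2 members higher when adjusted over the list alone. Jag1, a Notch ligand gene, stood at 2.99 and 7.05 CPM and the target gene Hes1 at 22.9 and 58.4 CPM.

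The p53 target and interferon-stimulated lists were higher. Of 18 p53 targets 2 rose, Gtse1 (log2 fold change 2.24, SE 0.34) and the death receptor gene Tnfrsf10b (1.87, SE 0.29), and 8 adjusted over the list alone (camera adjusted p = 9.98e-05, adjusted p = 0.269 with an estimated correlation). Gtse1 is also a cell cycle gene. Of 25 interferon-stimulated genes Xaf1 rose (1.52, SE 0.23), and 8 adjusted over the list alone (camera adjusted p = 2.01e-06, adjusted p = 0.269 with an estimated correlation). Of 25 acute phase proteins Saa1 rose from 28.0 ± 10.2 to 116 ± 19.7 CPM, and 4 adjusted over the list alone (camera adjusted p = 0.0382, adjusted p = 0.573 with an estimated correlation). The acute phase list was not called without control replicate 2, control replicate 3 or knockdown replicate 2 (camera adjusted p = 0.200, 0.172 and 0.0796). Its median member, relative to the mean of all libraries, lay at 0.24 on the log2 scale in control replicate 1, above the knockdown libraries at 0.10, 0.22 and 0.09. The 17 NF-kB and inflammatory cytokine genes and the 19 TGF-beta response genes passed by camera (adjusted p = 0.0313 and 0.0162, adjusted p = 0.492 for both with an estimated correlation), with 0 members past edgeR over all genes or adjusted over the list alone. Neither was called without control replicate 3 (camera adjusted p = 0.399 and 0.0736), nor the NF-kB list without knockdown replicate 1 or 2 (0.0522 and 0.134). With all libraries and a filter of 1 CPM in 3 libraries neither was called (camera adjusted p = 0.0719 for both). The fry test called none of the acute phase, NF-kB and TGF-beta lists (adjusted p = 0.224, 0.224 and 0.158). For the NF-kB and TGF-beta lists control replicate 1 lay within the range of the knockdown libraries, with median members at 0.27 and 0.19 on the log2 scale.

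Hepatocyte transcription factors and cytochrome P450 and conjugating enzymes were lower as lists. Of 17 hepatocyte transcription factors 2 fell, among them Nr1i3, and 2 adjusted over the list alone, and 16 had negative fold changes (camera adjusted p = 4.27e-05, adjusted p = 0.269 with an estimated correlation). Hnf4a stood at 937 ± 441 and 655 ± 80.3 CPM and did not pass (edgeR adjusted p = 0.544). The 43 cytochrome P450 and conjugating enzymes had a median log2 fold change of -0.50, with 0 members past edgeR over all genes and 4 lower adjusted over the list alone (camera adjusted p = 1.97e-05, adjusted p = 0.181 with an estimated correlation). Ugt1a1, which conjugates bilirubin, stood at 160 and 70.2 CPM (edgeR adjusted p = 0.0585), and Cyp2b10, a target of the receptor CAR, at 659 and 194 CPM (edgeR adjusted p = 0.0845). Both these lists were also called lower without control replicate 1 (camera adjusted p = 0.000923 for each, adjusted p = 0.562 for each with an estimated correlation). In the same livers camera called the matrix and macrophage lists higher, with medians of 1.02 and 0.84. Control replicate 1 lay at the knockdown level for the macrophage list. The endothelial list, with a median of 0.07, was not called.

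Of 16 heme synthesis and breakdown genes Alas1 fell, and 3 adjusted over the list alone (camera adjusted p = 0.0156, adjusted p = 0.492 with an estimated correlation). Fech, the ferrochelatase that DDC derivatives block, stood at 198 ± 26.2 and 189 ± 10.9 CPM (edgeR adjusted p = 0.894). The 15 bile acid synthesis genes were lower as a list (camera adjusted p = 0.0313, adjusted p = 0.349 with an estimated correlation), with 0 members past edgeR over all genes or adjusted over the list alone. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 441 ± 267 and 177 ± 33.8 CPM (edgeR adjusted p = 0.306) and fell by 1.73 on the log2 scale without control replicate 1 (edgeR adjusted p = 0.000246). Cyp8b1 (edgeR adjusted p = 0.619) and the bile salt exporter gene Abcb11 (edgeR adjusted p = 0.989) did not pass. Without control replicate 1 neither list was called by camera (adjusted p = 0.330 and 0.0668), nor was the bile acid synthesis list without control replicate 2 (adjusted p = 0.0577) or with all libraries and a filter of 1 CPM in 3 libraries (adjusted p = 0.0572). The fry test called neither (adjusted p = 0.0845 and 0.0503).

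The secreted proteins, urea cycle, cholesterol synthesis, ribosomal protein and female-biased lists were called lower by camera with all libraries (adjusted p = 0.0102, 3.01e-05, 0.0102, 7.70e-06 and 0.0411). With an estimated correlation their adjusted p were 0.573, 0.492, 0.552, 0.573 and 0.492. Without control replicate 1 they were not called (camera adjusted p = 0.732, 0.0837, 0.181, 0.294 and 0.205). Leaving out control replicate 2 also ended the calls of the cholesterol synthesis and female-biased lists (0.0577 and 0.178), and leaving out knockdown replicate 2 that of the cholesterol synthesis list (0.142). The female-biased list was also not called with a filter of 1 CPM in 3 libraries or by camera on ranks (0.0872 and 0.0794). The fry test called none of these lists (adjusted p = 0.387, 0.256, 0.379, 0.379 and 0.256). No member of these lists passed edgeR over all genes. Adjusted over the list alone, 3 female-biased genes and 0 of the others were lower. The abundant plasma protein gene Alb stood at 91706 ± 13218 and 87827 ± 5042 CPM (edgeR adjusted p = 0.944), Apoa2 at 3721 and 1950 CPM, and the urea cycle gene Arg1 at 2750 and 1387 CPM, neither of which passed.

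Of 18 male-biased liver genes, Selenbp2 rose from 76.2 ± 10.1 to 263 ± 50.6 CPM and Elovl3 from 0.535 to 3.94 CPM. Adjusted over the list alone, 4 were higher and 1 lower (camera adjusted p = 0.0156, adjusted p = 0.492 with an estimated correlation), and camera did not call the list without control replicate 1 (adjusted p = 0.243), nor did the fry test with all libraries (adjusted p = 0.100). No major urinary protein gene of this list (Mup20, Mup7, Mup12 or Mup21) passed edgeR over all genes. The major urinary protein genes Mup3, Mup10, Mup11 and Mup14, outside the list, were chosen after their values were seen, because they passed edgeR over all genes (adjusted p = 0.0384, 0.0104, 0.00985 and 0.0322). The family was not tested as a list. Their log2 fold changes were 3.02 (SE 0.45), 4.03 (SE 0.35), 4.28 (SE 0.35) and 3.42 (SE 0.46). They belong to a family of similar genes, some of them near-identical, so the reads of each are less certain.

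The remaining lists were not called by camera at the preset correlation with all libraries, though other settings called some of them. The 22 genes of BMP-SMAD signalling and iron regulation gave an adjusted p of 0.0621, with 1 member lower when adjusted over the list alone. Hamp, which encodes the iron hormone hepcidin, stood at 1541 ± 473 and 776 ± 246 CPM (edgeR adjusted p = 0.226), and Id1 at 55.0 ± 47.5 and 33.0 ± 12.7 CPM (edgeR adjusted p = 0.666). Periportal and pericentral hepatocyte genes gave camera adjusted p of 0.0580 and 0.0723, bile acid and organic anion transporters 0.417, and NRF2 targets 0.417. Adjusted over the list alone, 1 periportal gene was higher and 0 genes of the other lists passed. Of 24 genes of fatty acid oxidation the lipid droplet gene Plin2 rose from 153 ± 30.5 to 448 ± 49.5 CPM (camera adjusted p = 0.430 for the list), and of 21 genes of glycolysis and hypoxia Ndrg1 rose from 8.22 ± 0.194 to 22.2 ± 1.06 CPM (camera adjusted p = 0.606). Adjusted over the list alone, 1 gene of fatty acid oxidation was higher, and 1 gene of glycolysis was higher and 1 lower. Fatty acid synthesis (1 higher and 2 lower adjusted over the list alone) and the integrated stress response (2 higher adjusted over the list alone) each gave a camera adjusted p of 0.126. Mitochondrially encoded genes (0.0735), X-inactivation and Y-linked genes (0.643) and adipocyte and mesothelial genes (0.562) had 0 members past edgeR over all genes or adjusted over the list alone. Without control replicate 1 camera called the mitochondrially encoded and the X-inactivation and Y-linked lists lower (adjusted p = 0.00103 and 0.0115, adjusted p = 0.635 and 0.562 with an estimated correlation). With all libraries the offset for GC content and length moved their medians from -0.44 and -0.51 to -0.26 and -0.08. Camera called neither of these lists with the offset (adjusted p = 0.148 and 0.683). Leaving out control replicate 2, control replicate 3 or knockdown replicate 1 brought a camera call lower for BMP-SMAD (adjusted p = 0.0327, 0.0081 and 0.0249), and leaving out control replicate 2 one for periportal genes and fatty acid synthesis (0.00877 and 0.0468). With knockdown replicate 2 left out, the periportal, pericentral and mitochondrially encoded lists were called lower and NRF2 targets higher (0.00807, 0.0458, 0.0449 and 0.0123). With all libraries, camera called BMP-SMAD lower with the replicate block, the filter of 1 CPM, ranks and the offset for GC content and length (adjusted p = 0.0349, 0.0362, 0.0453 and 0.0248). It called the periportal list lower with the offset (0.0482), the pericentral list lower with the block (0.0494), and the mitochondrially encoded list lower with the block and on ranks (0.0149 and 0.0344). With knockdown replicate 3 left out, the mitochondrially encoded list was called lower and the integrated stress list higher (0.046 and 0.0163). Neutrophil, lymphocyte, pancreatic acinar and red blood cell lists had 2, 2, 2 and 1 tested members and were not tested as lists.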

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

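The offset for GC content and transcript length was chosen after seeing the data, as was log2(FPKM + 0.1) for Atoh8, and the other alternatives before. The number of called genes depended on the test and on single libraries. Genes higher and lower in knockdown numbered 213 and 34 with no filter, 636 and 298 with DESeq2, 2576 and 2512 with limma-voom quality weights, and 363 and 130 with the offset. With limma on log2(FPKM + 1), 107 were higher and 27 lower. All 119 genes were also called with the same direction by DESeq2 and limma-voom, 118 with the offset, 88 by limma on log2(FPKM + 1), 73 on log2(FPKM + 0.1) and 32 with the replicate block. On the simulated data with all 6 libraries DESeq2 made 48 false calls among 13483 genes, limma-voom 4 and edgeR 3. Those genes were drawn independently and no simulated library stood apart, so these counts may not carry over to the real data. The share of calls that were higher was 85.7% in edgeR, 68.1% in DESeq2, 50.6% in limma-voom, 73.6% with the offset and 50.7% without control replicate 1. Leaving out 1 library gave 0 to 2348 higher and 0 to 2284 lower genes, with the largest counts without control replicate 1. The cause was not tested beyond the simulated recovery. Krt19, with 0 to 5 reads per library, fell below the expression filter of the main fit and was not tested.

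Not all same-numbered samples deviated together (correlations 0.253, -0.082 and 0.29), so the numbers were not read as pairs. With the replicate number as a block, 33 genes were higher and 2 lower, 11 lists higher and 12 lower. Not every sample correlated best with its own number.

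The log2 fold change of Atoh8 was negative under every alternative run for it, with -1.41 on log2(FPKM + 0.1). It passed with DESeq2 (-1.91), limma-voom (-0.97), the offset (-1.74) and without control replicate 1, and ranged from -2.24 to -0.95 when 1 library was left out, with edgeR adjusted p from 0.0115 to 0.57. Gene lists higher and lower numbered 0 and 0 with an estimated correlation and 6 and 2 by fry (cholangiocyte, matrix, cell cycle, YAP, interferon and p53 lists higher, hepatocyte transcription factors and cytochrome P450 lower), and 7 to 12 and 4 to 11 when 1 library was left out.

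Genes that did not pass changed sign in some settings, and the cause was not tested. With limma-voom the log2 fold changes were -0.072 for Sox9, 0.016 for Alb, 0.22 for Cyp8b1, 0.24 for Id1 and 0.058 for Fech. With the offset they were -0.038 for Sox9 and 0.028 for Alb. Abcb11 reached 0.020 with no filter, 0.071 on log2(FPKM + 1) and 0.094 with the block. When 1 library was left out, Sox9 ranged from -0.11 to 0.25, Alb from -0.18 to 0.043, Cyp8b1 from -1.36 to 0.37, Abcb11 from -0.32 to 0.23, Id1 from -1.19 to 0.20 and Fech from -0.14 to 0.057.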

Other observations

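Chosen only after the result was seen were the tests of swapped libraries, other cells, the share of hepatocytes, cholangiocytes and both tests on clock genes, and the counts over other splits. The offset for GC content and transcript length was also added after seeing the data, though what it would show for control replicate 1, the cell cycle genes and Spp1 was written down before its result was seen.

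Values of some clock genes lay apart between the groups, in both directions, without passing the test with all libraries. Cry1, a repressor of the circadian clock, stood at 22.5 ± 8.89 CPM in controls and 5.79 ± 1.25 CPM in knockdown (SD, n = 3), and Nr1d1, another repressor, at 18.0, 6.77 and 2.89 CPM in control replicates 1 to 3 and 83.9, 68.0 and 77.6 CPM in knockdown replicates 1 to 3. Neither passed with all libraries (edgeR adjusted p = 0.0524 and 0.0801), and both passed without control replicate 1 (edgeR adjusted p = 0.000363 and 0.000109). Of the 17 clock genes tested 0 passed over all genes, and 2 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.430). Npas2 had 3 reads in the controls and 85 in the knockdown libraries, a ratio of 22.2 with an exact 95% counting interval of 7.34 to 110.

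A hypothesis is that the groups were collected at different times of day. The median log2 fold change of the day-phase genes Nr1d1 and Dbp lay 3.37 above that of Per2, Cry1 and Nfil3, which peak later. These genes were picked from the pattern itself, and the labels give no time of collection. Time of day and knockdown therefore cannot be told apart here, for clock genes or for other genes that differed. With the offset for GC content and length the difference was 3.66, which argues against that bias as its cause. An effect of the knockdown on the clock also stays open and was not tested.

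Control replicate 1 stood apart from the other controls. Its log2 difference from them followed GC content over genes, which are not independent replicates (Spearman 0.638, against 0.0352 between control replicates 2 and 3, 0.352 for the knockdown libraries against control replicates 2 and 3, and 0.328 for knockdown replicate 1 against the other knockdown libraries). The offset for GC content and length removed 43.6% of the variance of that difference, and the remaining spread was 1.79 times that between the other controls, which argues against this bias as the whole cause while part of the difference may come from it. A swap with a knockdown library is argued against by Atoh8, which stood 6.23 times as high as in the highest knockdown library, with no knockdown library at the level of a control. A different liver state, or a single sample from outside the group, stays open and was not tested.

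Cell cycle genes were higher in the knockdown livers for 11 of 25 members by edgeR over all genes. As a list they passed by camera at the preset correlation but not with an estimated one (camera adjusted p = 0.269). With the offset for GC content and length their median log2 fold change was 3.10, against 2.94 without it, and the 25th percentile was 1.79, which argues against that bias. A lower share of hepatocytes alone, with other cell types in unchanged proportions, would raise those types' lists alike and lower the hepatocyte lists. The 25th percentile of the matrix list lay 0.46 above the 75th percentile of the endothelial list on the log2 scale. Without control replicate 1 the gap between the highest and the lowest list was 0.80. These gaps argue against such an even shift as the whole cause. At the preset correlation camera called the hepatocyte transcription factor, secreted protein and cytochrome P450 lists lower, as a lower share would give. The secreted protein list was not called without control replicate 1 (camera adjusted p = 0.732), with a median log2 fold change of 0.04. The transcription factor and cytochrome P450 lists stayed lower without that library (camera adjusted p = 0.000923 for each). With all libraries the periportal and pericentral lists were not called (camera adjusted p = 0.0580 and 0.0723). A lower share with uneven change among the other cells therefore stays open. Camera called the matrix and macrophage lists higher but not the Kupffer cell and endothelial lists (adjusted p = 0.126 and 0.841), whose 25th percentiles were 0.074 and -0.058, so more cells of some types stay open, and dividing cells of another type cannot be told apart from dividing hepatocytes in RNA from whole samples. An effect of the knockdown is the biological explanation the design names, and it stays open.

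Spp1 rose without the keratins of bile duct cells. The 75th percentile of the log2 fold changes of the other 17 tested cholangiocyte markers was 1.19, against 3.67 for Spp1 (SE 0.28). Krt19, Krt7 and Epcam reached at most 1.35 CPM in any knockdown library. These values argue against cholangiocytes as the whole source. Among the other markers Prom1 rose by a log2 fold change of 2.95 (SE 0.42). The list, with Spp1 in it, passed by camera (adjusted p = 0.00182, adjusted p = 0.465 with an estimated correlation). With the offset for GC content and length the log2 fold change of Spp1 was 3.64, which argues against that bias. Expression in hepatocytes or macrophages may account for the rise, as a hypothesis that was not tested. In control replicate 1 the median macrophage marker lay at 0.51 on the log2 scale, relative to the mean of all libraries. The knockdown libraries lay at 0.60, 0.45 and 0.59. Spp1 stood at 30.7 CPM in control replicate 1 and at 539, 322 and 528 CPM in the knockdown libraries. Macrophage markers at the knockdown level thus came without high Spp1 there, but this rests on 1 library that stood apart.

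The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 102 genes higher and 17 lower, where the highest other split gave 0 in either direction, and it was the 1 split with counts as large for genes higher, genes lower, gene lists higher and gene lists lower. For lists the real split gave 11 higher and 9 lower, and the highest count of another split in a single direction was 8, where which side is higher is arbitrary. In total the real split called 20 lists and the other splits 6 to 13, so list calls arose in groupings that mix controls and knockdown libraries.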
